A study of Homo sapiens with 13 samples.

How the data were processed

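RNA of peripheral blood T cells from children with immune thrombocytopenia (ITP), an autoimmune disease in which platelets are destroyed, was measured on 13 expression arrays. There were 7 newly diagnosed patients and 6 patients with chronic disease, and each array held the cells of 1 patient. Per the labels, mononuclear cells were separated on a density gradient, CD14-positive cells were removed and CD3-positive cells were then selected with magnetic beads and snap-frozen. Total RNA was amplified to cDNA and labelled with biotin using commercial kits.

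The deposited data give a linear signal intensity for each of 54675 probe sets, named as on an Affymetrix 3' expression array. The values are whole numbers, and the mean left after trimming 2% from each end was 500.1 on all 13 arrays, so the deposited signals carry a scaling to a common trimmed mean. The software that made them is not given in the sources used here. The median signal ran from 55 to 74 over the arrays, and Pearson correlations between arrays over all probe sets ran from 0.8927 to 0.9517, so no array was a copy of another.

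The design foresaw log2 values or the log2 of linear ones; the deposited data held linear signals with zeros, so log2(signal + 16) was taken. The pseudocount of 16 was set after the scale was seen and before any test. On this scale the difference of a gene with low signal is smaller than its true ratio. No further normalization was applied.

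Of the probe sets, 41091 named exactly 1 gene, 1801 named several genes, 11721 had no listed gene, and 62 were controls. Genes were named by Entrez identifier, of which 19735 of 19777 were in the reference gene table, used here for names and to find Y-linked and X-linked genes. Probe sets of Y-linked genes, XIST and TSIX, 95 in all, were left out of every test because the samples came from people. Each of 19740 genes was represented by its probe set with the highest mean over all arrays. Genes were tested if that mean reached the 40th percentile of all probe sets, a log2 of 5.52 or a signal of 29.7, which left 12872 genes. Where a gene's other probe sets are counted, only those whose mean reached the same limit are included. The mean of probe sets takes in the dimmer ones too. Background was taken as the 95th percentile of 27 bacterial control probe sets that match nothing in the sample, a log2 of 5.78 or a signal of 39. For 357 tested genes both group means were at or under it. A fold against a group in which no array exceeded the background is given as a lower bound against that level, and where a group mean lay under it with some arrays above, no size is given for the gene.

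Newly diagnosed and chronic samples were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at default settings, no covariate, two-sided tests and Benjamini-Hochberg adjustment over all genes tested; an adjusted p under 0.05 was called a difference. Differences are newly diagnosed minus chronic. Tables were read with data.table (version 1.17.8), and plots were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The p-values treat patients as separate samples. The number of arrays limits the precision: the median standard error (SE) of a difference was 0.263 on the log2 scale. When tested on simulated data of the same size with 200 changed genes among 12872, the fit called 1.49% of genes changed by 0.5 log2, 40.3% of those changed by 1 and 84.8% of those changed by 2, and 6 of its 90 calls were unchanged genes. The simulation drew each gene on its own from a normal distribution, without correlation between genes or differences between arrays. Its shares may therefore not hold for the real arrays.

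The comparison, the tests, the filter, 24 gene lists, 8 lists of marker genes of other cell types and the rule for naming genes were fixed before the data were examined. The lists cover T cell identity, T cell receptor signalling, naive and central memory, cytotoxic effector, T helper 1, T helper 2, T helper 17, innate-like, regulatory and follicular helper T cells, inhibitory receptors, type I interferon response, interferon gamma response, early activation, NF-kappaB inflammation, cell cycle, apoptosis, glucocorticoid response, oxidative stress, cytokines, cytokine receptors, heat shock and unfolded protein, ribosomal proteins and oxidative phosphorylation. The marker lists cover monocytes, neutrophils, B cells, plasma cells, natural killer cells, platelets, erythroid cells and dendritic cells. All 32 lists were tested with limma's camera, which asks whether a list's genes differ more than other genes do, with a preset inter-gene correlation of 0.01 and adjustment over the 32 lists; at least 5 tested members were needed. The same test with a correlation estimated from each list, camera on ranks, and fry, a rotation test of whether a list's genes move one way, were run beside it. The mean log2 level of each list on each array was compared between groups with a two-sided exact permutation test over the 1716 ways to divide the samples. For marker lists that test was planned; for the other lists it was chosen after the data were seen.

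Genes were named by this rule: the 12 called genes with the largest difference in each direction; of each list the members past the adjusted p over all genes or over the list alone, at most 8, and otherwise up to 4 members with the smallest p; and CD3D, CD3E, CD3G, CD4, CD8A, CD8B and CD14 as a check of the cell selection. HLA, KIR, GSTM and GSTT genes and receptor segments were not eligible as top genes, since array probes in them also read inherited variants. Other genes named are said to be so.

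The alternatives fixed in advance were the mean of a gene's probe sets, every probe set on its own, no filter, a filter at the 60th percentile, quantile normalization, centring each array on its median, eBayes with trend and robust, array weights, a block for the replicate number, covariates for monocyte, platelet, erythroid and B cell markers and for the first residual component, an added 1.5-fold minimum, an adjusted p under 0.10, X-linked genes left out, and each sample left out in turn. Alternatives chosen after the data were seen were pseudocounts of 1 and 64, covariates for the hybridisation controls, for the ratio of 3' to 5' ACTB probe sets and for plasma cell markers, leaving out the 4 newly diagnosed arrays with bright hybridisation controls, and the exact test of list levels in place of camera. Hybridisation controls are labelled bacterial transcripts added to each sample just before it goes on the array.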

Results

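Transcript levels of CD3-selected blood T cells were measured in 13 children with ITP, 7 newly diagnosed and 6 with chronic disease, on 1 array each. All values below are log2(signal + 16) of the deposited signals, given as mean ± standard deviation (SD) per group, and differences are newly diagnosed minus chronic. Median log2 levels of the tested genes were close on all arrays, between 9.04 and 9.21.

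The comparison asked which transcripts of T cells separate newly diagnosed from chronic disease. The CD3-selected cells of newly diagnosed children held more RNA of the transcription factor gene TOX2, the sulfotransferase gene CHST2, the Notch pathway gene DTX1, the kinetochore gene ZWINT and the core histone genes H2AC6 and H2BC12. They held less RNA of the nuclear receptor genes RORA and NR1D2 and of the zinc finger gene TSHZ2. DTX1, H2AC6 and H2BC12 passed in only 3, 3 and 2 of 13 runs that left out 1 sample. RORA, TSHZ2, NR1D2 and ZWINT passed in 3, 5, 5 and 7 of these runs. With the mean of probe sets, TOX2 and ZWINT passed and the other genes named here did not, with RORA at -0.64 (adjusted p = 0.148). Without the 4 arrays with bright hybridisation controls, and with the hybridisation or plasma cell covariate, limma called 0 genes. In these runs the differences kept a median share of 0.921, 0.946 and 0.898 of their size. By camera with its preset correlation, cell cycle, oxidative phosphorylation, ribosomal protein and T cell identity genes were higher as groups than other genes. T helper 17 genes were lower. That test calls lists too readily in these samples: 67 of 100 splits of the samples, the real one included, gave at least 5 lists. The median of the other splits was 6. With an estimated correlation 0 of these 5 lists passed. The interferon and regulatory T cell lists did not pass, and the cytotoxic effector list passed only in alternatives.

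Of 12872 genes tested with limma, 32 differed at an adjusted p under 0.05, 16 higher and 16 lower in newly diagnosed patients. The called differences ran from 0.78 to 2.11 in size on the log2 scale. At an unadjusted p under 0.05 there were 2364 genes, 1383 higher and 981 lower, where chance gives about 644. The groups did not overlap in 26 of the 32 genes, and in 181 of all tested genes; chance gives 0.117% of genes, or about 15. Adjusted p-values of 17 of the 32 genes lay between 0.048 and 0.05, and the number called was not steady. Leaving out chronic sample 1, 2, 3, 4, 5 or 6 gave 6, 3, 91, 3, 4 and 2 genes, and leaving out newly diagnosed sample 1, 2, 3, 4, 5, 6 or 7 gave 12, 18, 8, 6, 116, 10 and 6. Quantile normalization gave 18 genes higher and 7 lower.

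TOX2, which encodes an HMG-box factor found in follicular helper T cells, was 8.26 ± 0.54 (SD, n = 7) in newly diagnosed and 6.18 ± 0.51 (SD, n = 6) in chronic samples, a difference of 2.08 (SE 0.28, adjusted p = 0.0152). CHST2, which encodes an enzyme that adds sulfate to glycans such as selectin ligands, was 9.94 ± 0.45 and 8.13 ± 0.40, a difference of 1.81 (SE 0.24, adjusted p = 0.0152). The groups did not overlap for either gene, and TOX2 and CHST2 stayed past the threshold in all 13 runs that left out 1 sample. With the mean of probe sets CHST2 differed by 1.13 (adjusted p = 0.0514). ZWINT was 11.23 ± 0.51 and 9.70 ± 0.28, a difference of 1.53 (adjusted p = 0.0245), and passed in 7 of those 13 runs. DTX1, a ubiquitin ligase gene that is a target of Notch signalling, was 8.34 ± 0.20 and 6.78 ± 0.81, a difference of 1.56 (adjusted p = 0.0488). It passed in 3 of 13 runs. The histone genes H2AC6 and H2BC12, whose products package DNA, were higher by 1.53 and 1.04 and passed in 3 and 2 of the runs. Among other genes higher in newly diagnosed samples, PCBP3, an RNA-binding protein gene, differed by 1.24, with 4 of 6 chronic arrays above the background, and passed in 8 of 13 runs. SLC12A4, which encodes a potassium and chloride cotransporter, was higher (adjusted p = 0.0328), with 7 of 7 newly diagnosed and 3 of 6 chronic arrays above the background. VASP, an actin regulator, differed by 1.26 and PGAP2, a gene of GPI-anchor remodelling, by 1.13. RAP1GAP, which encodes an inhibitor of the small GTPase RAP1, exceeded the background on 6 of 7 newly diagnosed and 0 of 6 chronic arrays, at least 1.35-fold higher. C16orf95 differed by 2.08 (adjusted p = 0.0488), but its 1 other probe set above the brightness limit did not go the same way, and with the mean of probe sets it differed by 0.54 (adjusted p = 0.199). The remaining 4 higher genes, outside the naming rule, were ATPAF1, HMGA1, KPNA2 and PPM1G, with differences of 0.78 to 1.00.

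TSHZ2, which encodes a zinc finger transcription factor, was 8.49 ± 0.78 in newly diagnosed and 10.57 ± 0.57 in chronic samples, a difference of -2.08 (SE 0.35, adjusted p = 0.0345), and 4 of 4 other probe sets went the same way. RORA, which encodes a nuclear receptor used in T helper 17 differentiation and in the circadian clock, was 10.11 ± 0.41 and 11.60 ± 0.50, a difference of -1.49 (SE 0.25, adjusted p = 0.0345), with 6 of 6 other probe sets in the same direction. The RORA difference was -0.44 without chronic sample 1 and -0.56 without chronic sample 6, when another probe set became the brightest, and it passed in 3 of 13 runs that left out 1 sample. NR1D2, which encodes the clock repressor REV-ERB beta, was 10.85 ± 0.39 and 12.10 ± 0.27, a difference of -1.26 (SE 0.20, adjusted p = 0.0328), and passed in 5 of the runs. NOTCH2NLA differed by -1.33 (adjusted p = 0.0237) and passed in 10 of the runs; its near-identical paralogs can bind the same probes. MID2, an X-linked ubiquitin ligase gene, differed by -2.11 (adjusted p = 0.0488). ZNF662 differed by -1.77, the desmosomal cadherin gene DSC1 by -1.66, the vesicle-trafficking gene NBEA by -1.50, the mitochondrial dehydrogenase gene ADHFE1 by -1.39 and MIER3 by -1.37. With the mean of probe sets several of these genes had smaller differences that did not pass: TSHZ2 (-1.31, adjusted p = 0.0564), RORA (-0.64, 0.148), MID2 (-1.39, 0.0863), NBEA (-0.91, 0.127) and MIER3 (-0.43, 0.308). RGMB, a co-receptor gene of bone morphogenetic proteins, differed by -1.27 and the ubiquitin protease gene USP31 by -1.25, but 1 of 3 and 1 of 2 of their other probe sets went the same way. With the mean of probe sets the differences were -0.60 for RGMB (adjusted p = 0.205) and -0.097 for USP31 (adjusted p = 0.813). The other 4 lower genes, also outside the naming rule, were KIF5C, NUDT9, CA5B and SNX14, with differences of -1.20 to -1.08.

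**Figure D1:**
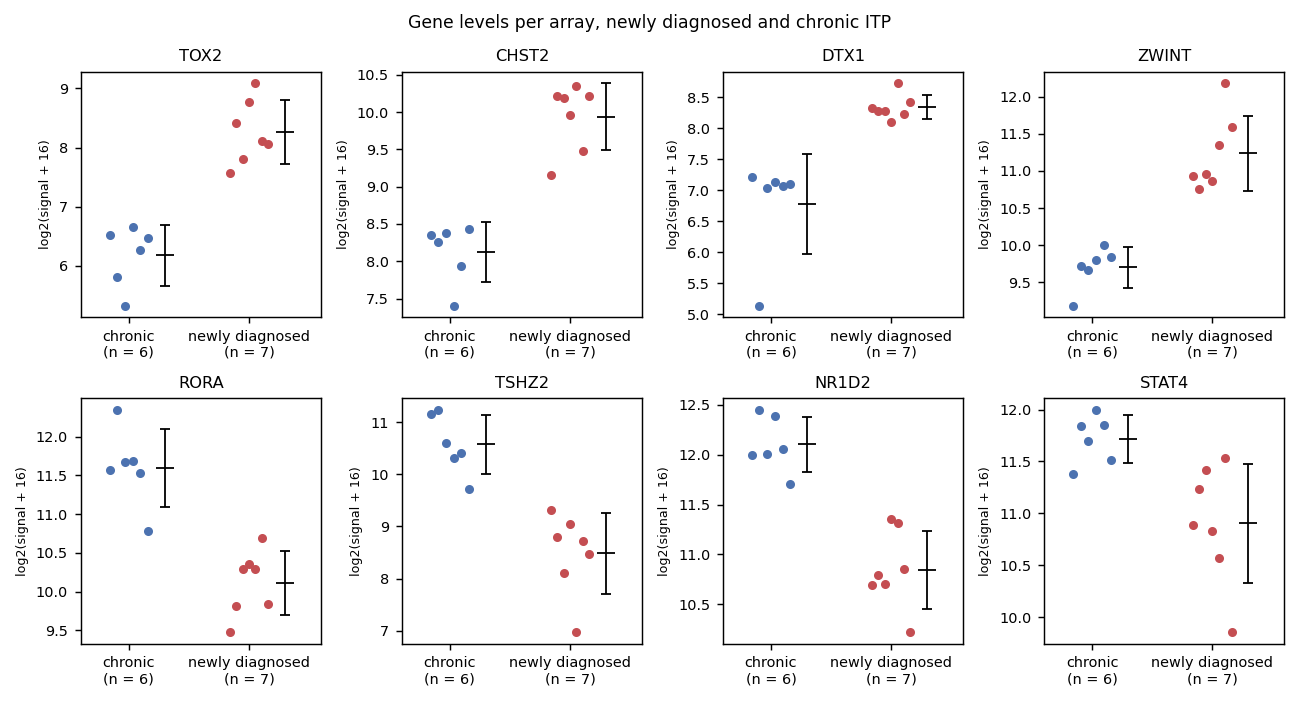
Levels of 8 genes, 1 point per array, on the log2(signal + 16) scale, with bars for the group mean ± SD. TOX2, CHST2, DTX1 and ZWINT lie higher in newly diagnosed samples, and RORA, TSHZ2, NR1D2 and STAT4 lie lower, STAT4 only adjusted over its list alone.

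Cell cycle genes had the highest median of the 5 lists that passed. Of 25 measured, 24 had a positive difference, with a median of 0.79 (camera adjusted p = 2.7e-06). Over all genes 1 was higher, ZWINT, and 9 were higher adjusted over the list alone, with 16 not passed. Those 9 were the mitotic cyclin gene CCNB2 (difference 1.71), CDC20, ZWINT, the proliferation marker MKI67, the nucleotide synthesis genes RRM2 (1.48) and TYMS (1.40), the mitotic kinase gene AURKA (1.41), the replication gene MCM2 (1.04) and PCNA (0.79), which the limit of 8 left out of the naming rule. CDC20 and MKI67 exceeded the background on 2 of 6 chronic arrays each and on 6 and 5 of 7 newly diagnosed arrays. The list's mean level was 8.36 ± 1.02 in newly diagnosed and 7.45 ± 0.20 in chronic samples, with 4 of 7 newly diagnosed arrays above every chronic array (two-sided exact permutation p = 0.0507). The members rose and fell together across arrays: with the estimated correlation of 0.639 the adjusted p was 0.799, and by fry it was 0.20. With the preset correlation the camera call held in all 13 runs that left out 1 sample. Medians ran from 0.59 without newly diagnosed sample 5 to 1.02 without newly diagnosed sample 7. All these runs share that correlation, so they cannot show that the call would hold without it. The cell cycle median was 1.23 without the 4 arrays with bright hybridisation controls and 1.37 with the hybridisation covariate.

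Oxidative phosphorylation genes, which encode the mitochondrial respiratory chain and ATP synthase, had a positive difference in 16 of 18 members, with a median of 0.37 (camera adjusted p = 4.8e-04, adjusted p with the estimated correlation 0.663, fry adjusted p = 0.0183). Over all genes 0 passed in limma, and 5 were higher adjusted over the list alone, with 13 not passed. These were ATP5PO (0.82), COX5A (0.59), NDUFB3 (0.55), NDUFA9 (0.49) and ATP5F1A (0.46). The mean level was 11.86 ± 0.16 and 11.51 ± 0.15, higher on 5 of 7 newly diagnosed arrays than on any chronic array (exact permutation p = 0.00291, 0.0373 adjusted over the 32 lists). Ribosomal protein genes had a positive difference in 24 of 27 members, with a smaller median of 0.22 (camera adjusted p = 0.00471, with the estimated correlation 0.799). None passed, with 0 over all genes and 0 adjusted over the list alone. The largest of the 4 members named were RPS28 (0.54), with 0 of 2 other probe sets in the same direction, and RPL10A (0.35). The ribosomal protein call was lost under quantile normalization (median -0.047, adjusted p = 0.264), with the mean of probe sets (0.16, 0.0743), with the hybridisation covariate (0.068, 0.463), by fry (adjusted p = 0.20) and by the exact permutation test of its mean level (adjusted p = 0.234).

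T helper 17 genes had a negative difference in 6 of 8 measured members, with a median of -0.52 (camera adjusted p = 0.0317, with the estimated correlation 0.400, fry adjusted p = 0.0139). RORA was lower over all genes, and RORA and the interleukin-23 receptor gene IL23R were lower adjusted over the list alone, with 6 not passed. IL23R exceeded the background on 1 of 7 newly diagnosed and 5 of 6 chronic arrays, so the size of its difference was not measured. The chemokine receptor gene CCR6 and the lectin gene KLRB1 differed by -0.60 each and did not pass. The list median was -0.87 without the 4 arrays with bright hybridisation controls. With no filter on dim genes it was 0.12, although the test still pointed down, and the list did not pass. The call was also lost with the mean of probe sets (adjusted p = 0.195), the filter at the 60th percentile (0.124), a pseudocount of 1 (0.143) and camera on ranks (0.0785), without newly diagnosed sample 3 (adjusted p = 0.0735) and without chronic samples 1, 2 and 6 (adjusted p 0.101, 0.0870 and 0.312). The mean level of all 13 measured members, dim ones included, was 7.85 ± 0.17 and 8.14 ± 0.19 (exact permutation p = 0.0157, 0.0839 adjusted over the 32 lists).

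T cell identity genes were positive in 12 of 14 members, with a median of 0.27 (camera adjusted p = 0.0495, with the estimated correlation 0.799); 0 passed over all genes and 0 adjusted over the list alone. The T cell receptor kinase gene LCK (0.54), CD6 (0.47), the adaptor gene LAT (0.46) and CD3G (0.35) were the members of smallest p. The call was lost with the mean of probe sets (adjusted p = 0.116), the filter at the 60th percentile (0.0617), quantile normalization (0.20) and fry (0.0599), and without the 4 arrays with bright hybridisation controls (0.0661). Among runs that left out 1 sample it held in 4 of 13, those without newly diagnosed samples 5 and 7 and chronic samples 3 and 4, and was lost in the other 9 (adjusted p up to 0.105, without newly diagnosed sample 4). T cell receptor signalling genes did not pass (median 0.27, adjusted p = 0.308).

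**Figure D2:**
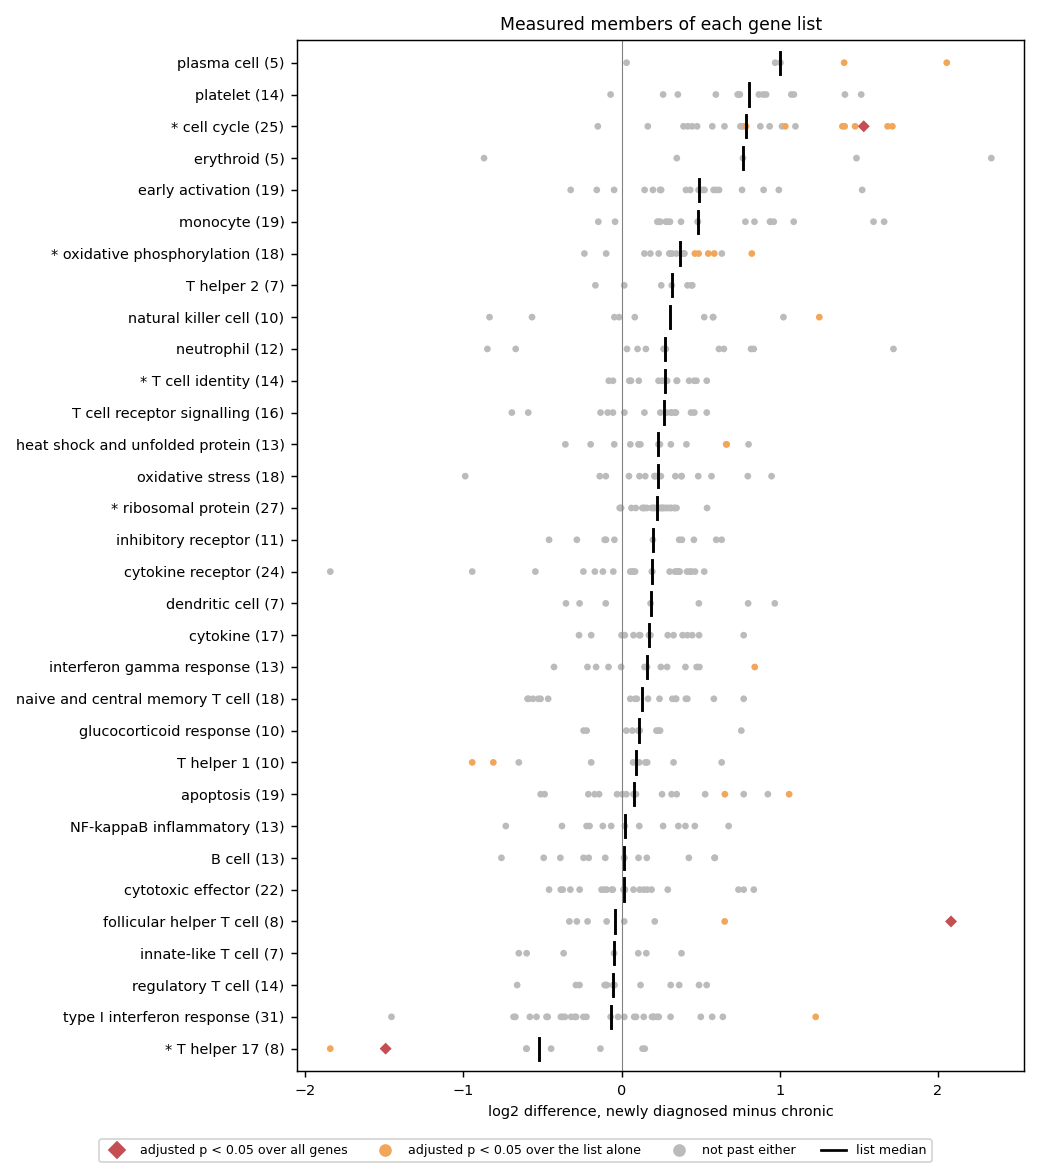
Log2 difference, newly diagnosed minus chronic, of each measured member of the 32 lists; diamonds mark members past the test over all genes, orange marks members past it adjusted over the list alone, grey marks the others, the number measured is in parentheses, black bars are list medians and stars mark lists with a camera adjusted p under 0.05. The cell cycle list has the highest median among the 5 starred lists, 0.79, and T helper 17 the lowest, -0.52.

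Other helper cell lists did not pass, with adjusted p-values of 0.470 for T helper 1, T helper 2, innate-like and follicular helper T cells and 0.825 for regulatory T cells. In the T helper 1 list the interleukin-18 receptor gene IL18R1 (-0.94) and the interleukin-12 signalling gene STAT4 (-0.81) were lower adjusted over the list alone, 2 of 10 members, with 0 over all genes; the list's median was 0.09 while its mean was -0.11 and camera pointed down. In the follicular helper list TOX2 passed over all genes, and TOX2 and the costimulatory receptor gene ICOS (0.65, all-gene adjusted p = 0.0874) were higher adjusted over the list alone, 2 of 8 members; its median was -0.04 while its mean was 0.26 and camera pointed up. The regulatory T cell list had 0 of 14 members past either adjustment, FOXP3 among them (0.54), with a median of -0.05, a mean of 0.01 and camera pointing down. The naive and central memory list (0 of 18 members) and the cytotoxic effector list (0 of 22 members) each had an adjusted p of 0.855; the cytotoxic median was 0.02 and its mean 0.05 while camera pointed down. The cytotoxic effector list passed upward with the hybridisation covariate (median 0.87, adjusted p = 4.7e-04) and without the 4 arrays with bright hybridisation controls (0.44, 0.00969). Inhibitory receptors did not pass (0 of 11 members, adjusted p = 0.699).

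Type I interferon response genes did not differ as a list (31 measured, median -0.07, adjusted p = 0.470). The interferon-induced gene IFI27 was higher adjusted over the list alone, with 30 members not passed; it exceeded the background on 6 of 7 newly diagnosed and 0 of 6 chronic arrays, at least 1.64-fold higher. In the interferon gamma list (adjusted p = 0.456) the tRNA synthetase gene WARS1 (0.84) was higher adjusted over the list alone, 1 of 13 members. Early activation genes had a median of 0.49 and did not pass (adjusted p = 0.0870), with the AP-1 genes JUN (1.52) and JUNB (0.76) past neither adjustment. The early activation list passed without newly diagnosed sample 5 (adjusted p = 0.0426), without chronic sample 6 (0.00120) and with the plasma cell covariate (3.9e-04, median 0.82), and its median was 0.28 without newly diagnosed sample 7 (adjusted p = 0.226). Over all 31 alternatives its lowest median was -0.023, in a run other than those that left out 1 sample. The apoptosis list did not pass (adjusted p = 0.470), but the survival genes BCL2L1 (1.06) and MCL1 (0.65) were higher adjusted over the list alone, 2 of 19 members. Past neither adjustment, the survival gene BCL2 had a negative difference (-0.51) and the cell death gene BCL2L11 a positive one (0.53). The 1 other probe set of BCL2L1 above the brightness limit did not go the same way as the chosen one. In the heat shock and unfolded protein list (adjusted p = 0.151, fry adjusted p = 0.0183), which also passed with the platelet covariate (0.0495), the co-chaperone gene DNAJB1 (0.67) was higher adjusted over the list alone, 1 of 13 members. The mean levels of the apoptosis and heat shock lists were higher by 0.19 and 0.23, on 7 and 6 of 7 newly diagnosed arrays above every chronic array (exact permutation p = 0.00117 and 0.00350; both 0.0373 adjusted over the 32 lists). The remaining lists passed neither camera nor the exact test: oxidative stress (adjusted p = 0.151, although by fry it passed with 0.0315), cytokine (0.341), cytokine receptor (0.664), glucocorticoid response (0.699) and NF-kappaB inflammatory (0.893), with 0 members past either adjustment.

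Markers of other cell types were read beside these groups. Plasma cell markers were higher on 6 of 7 newly diagnosed arrays than on any chronic array, with a mean level of 8.50 ± 1.09 and 7.40 ± 0.68 (exact permutation p = 0.0606, 0.480 adjusted over the 8 marker lists) and a camera adjusted p of 0.0722. SDC1 and TNFRSF17 (1.41), surface proteins of plasma cells, were higher adjusted over the list alone, 2 of 5 members; SDC1 exceeded the background on 6 of 7 and 3 of 6 arrays. JCHAIN, the gene of the antibody joining chain, was 11.80 ± 1.01 and 10.80 ± 0.71. The plasma cell list passed with the mean of probe sets (camera adjusted p = 0.0117), no filter (0.0429), a pseudocount of 64 (0.0218) and the ACTB covariate (0.0492), and without newly diagnosed sample 2 (2.6e-04, median 1.46). Its median was 1.005 in the main fit and 0.56 without the 4 arrays with bright hybridisation controls (camera adjusted p = 0.470). With the mean of these markers as a covariate, chosen after the data were seen, limma called 0 genes (1354 at an unadjusted p under 0.05), and the differences of the 32 genes kept a median share of 0.898 of their size. Platelet markers had a median difference of 0.81 (camera adjusted p = 0.0722) and 0 members past either adjustment. The platelet list passed with the mean of probe sets (adjusted p = 0.0364), no filter (0.0292), a pseudocount of 64 (0.0180) and camera on ranks (0.0393), without newly diagnosed sample 5 (median 1.11, adjusted p = 0.00282) and without newly diagnosed sample 6 (1.17, 0.00323), and its median was 0.34 without newly diagnosed sample 7 (adjusted p = 0.441) and -0.21 without the 4 arrays with bright hybridisation controls (adjusted p = 0.470). The monocyte list had a median of 0.48 and did not pass (adjusted p = 0.151). It passed without newly diagnosed sample 2 (adjusted p = 0.0443), newly diagnosed sample 5 (0.0180) or chronic sample 6 (0.0265), and its median was -0.05 without newly diagnosed sample 7 (adjusted p = 0.993). Without the 4 arrays with bright hybridisation controls and with the hybridisation covariate the monocyte list passed downward (medians -0.58 and -0.94). Natural killer cell markers (0.470), erythroid markers (0.467), neutrophil, B cell and dendritic cell markers (0.699 each) did not pass. SH2D1B, a natural killer cell adaptor gene, was higher adjusted over the list alone, 1 of 10 members, and exceeded the background on 6 of 7 newly diagnosed and 1 of 6 chronic arrays. With the plasma cell covariate the B cell list passed downward (median -0.70, adjusted p = 0.0165). In the fit without covariates the B cell list's median was 0.02 while its mean was -0.02 and camera pointed down. By the exact permutation test, adjusted p-values of the marker levels ran from 0.480 to 0.972.

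**Figure D3:**
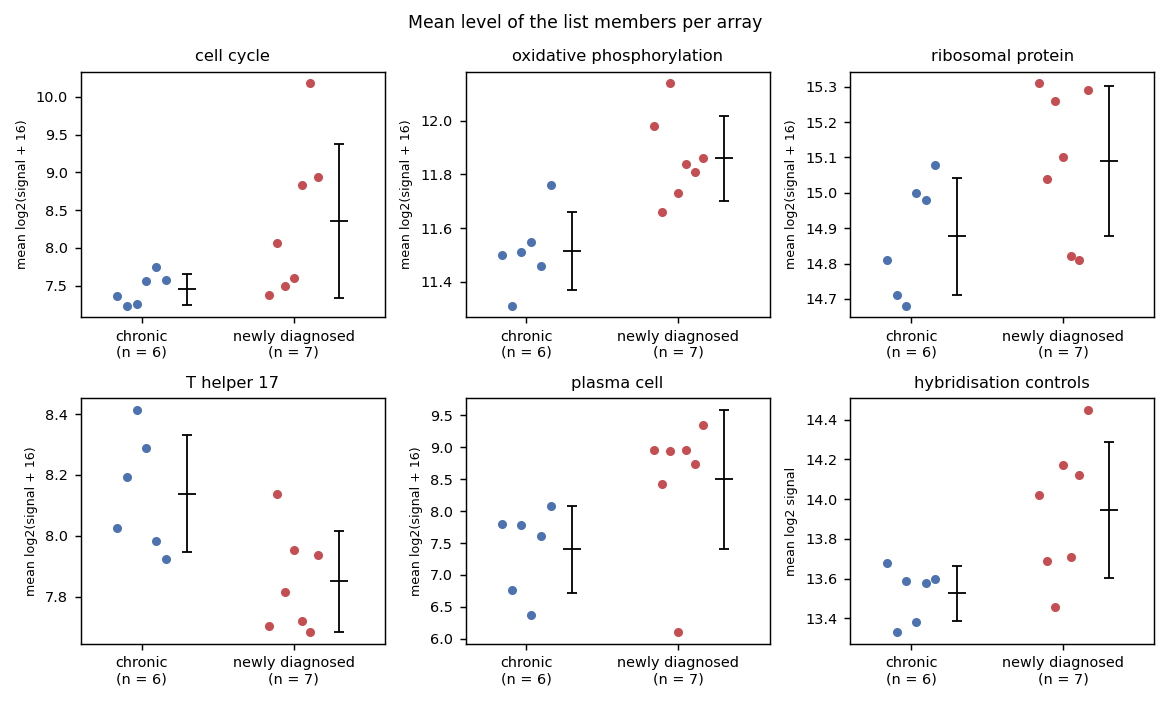
Mean log2 level per array of 5 lists and of the hybridisation controls, by group, 1 point per array, with bars for the group mean ± SD. Plasma cell markers are above every chronic array on 6 of 7 newly diagnosed arrays, and cell cycle genes on 4 of 7.

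The T cell markers CD3D (14.16 ± 0.19 and 13.81 ± 0.26), CD3E (11.64 ± 0.33 and 11.35 ± 0.24), CD4 (10.75 ± 0.60 and 10.26 ± 0.31), CD8A (13.70 ± 0.91 and 13.82 ± 0.25) and CD8B (11.33 ± 0.84 and 11.26 ± 0.64) did not differ by limma, with adjusted p-values of 0.271, 0.421, 0.342, 0.887 and 0.946. CD14, the monocyte receptor gene, exceeded the background on 3 of 7 newly diagnosed and 3 of 6 chronic arrays.

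The arrays themselves differed between the groups. The mean level of 18 hybridisation control probe sets was 13.95 ± 0.34 in newly diagnosed and 13.53 ± 0.14 in chronic samples (two-sided exact permutation p = 0.0204), and on newly diagnosed arrays 1, 4, 6 and 7 it was more than 0.2 above every chronic array. Without these 4 arrays limma called 0 genes (1436 at an unadjusted p under 0.05), while the 31 genes still tested kept a median share of 0.921 of their size, and the ribosomal protein median was 0.070 (adjusted p = 0.693). With the control level as a covariate limma also called 0 genes (1151 at an unadjusted p under 0.05). Newly diagnosed sample 7 had a ratio of 3' to 5' ACTB signal of 68.2, which rises with RNA degradation or incomplete amplification, where the other arrays ran from 3.77 to 19.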

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

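The regroupings of the samples were planned; the tests on bright arrays, plasma cells, a lone array and the deposited scaling were chosen after the results were seen. Of 132 groups of per-sample values examined, 10 had a sample far from the others of its group, where chance gives about 1 in 20 groups, or 7 here. Newly diagnosed sample 7 accounted for 4 of the 10. Its log2 ratio of 3' to 5' ACTB signal was 6.092 (2.490 to 3.631 in the others of its group), its erythroid marker level 7.855 (5.344 to 5.934), its CD8A level 11.68 (13.77 to 14.30) and its ADHFE1 level 8.299 (9.014 to 9.324). In newly diagnosed sample 1 the regulatory T cell list was 8.504 (7.844 to 8.028), and in newly diagnosed sample 2 the plasma cell markers were 6.102 (8.420 to 9.353). Chronic sample 1 was low for the apoptosis list, 9.841 (10.13 to 10.19), and for DTX1, 5.129 (7.033 to 7.209). MID2 was 10.27 in chronic sample 6 (8.615 to 9.150), and ZNF662 was 9.320 in chronic sample 2 (10.64 to 11.01).

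The first pattern weighed is the 32 genes that differed. Of 100 splits of the 13 samples, drawn from 1716 possible and including the real one, 2 gave as many genes and 91 of the others gave 0. Chance is thus an unlikely source, but it is not excluded, since few of the possible splits were drawn and the count itself was not steady. The highest other split gave 67 genes, and it moved newly diagnosed sample 5 out of its group, without which sample the real groups gave 116. The 4 bright arrays stay open as a cause: without them the called genes kept a median 0.921 of their size while their SE grew 1.21-fold, and 0 passed in limma (1436 at an unadjusted p under 0.05). Plasma cells among the selected cells, which the CD3 selection would remove, stay open too: with their marker mean as a covariate the called genes kept a median 0.898 of their size while their SE grew 1.17-fold, and 0 passed in limma (1354 at an unadjusted p under 0.05). The called genes were picked for a small spread within groups, so the size they kept excludes neither cause, and disease stage also stays open and untested.

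For the second pattern, the higher cell cycle list, chance cannot be excluded for the number of lists called: 67 of the 100 splits gave as many as the real 5, the highest other 13 and the median 6, so the preset correlation calls lists too readily in these samples. The bright arrays lay below the other newly diagnosed arrays (-0.999 of the group difference, SD 0.875 over 35 splits, where 1.75 was predicted). This ratio leans on newly diagnosed sample 5, an array without bright controls, at 10.18. Newly diagnosed samples 2 and 3 were at 7.60 and 8.83, and the bright arrays ran from 7.38 to 8.94. The ratio was not computed without sample 5, so the bright arrays stay open as a source. Newly diagnosed sample 5 alone stays open: without it the difference in mean level was 0.598 (SE 0.292, exact permutation p = 0.0714). Plasma cells stay open as a source: with their marker covariate the list median was 0.72 and camera with its preset correlation still passed (adjusted p = 3.9e-04), but the difference in mean level per array was 0.643 (SE 0.508) in place of 0.902, and 2 SE on either side reach both 0 and the full difference. A larger share of dividing T cells at diagnosis may be a biological source and stays untested.

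The third pattern is the higher ribosomal protein list. Under quantile normalization its median was -0.0466 (adjusted p = 0.264) while the median of all genes was 0.0573, as predicted if the deposited scaling of the arrays were the source. Quantile normalization makes the brightest values equal on all arrays, and this list's mean levels lay between 14.7 and 15.3. It would therefore also remove a real rise, so this test cannot decide and the deposited scaling stays open. The bright arrays stay open as a source: their ratio was 1.45 (SD 0.758 over 35 splits) against 1.75 predicted, and without them the list did not pass (adjusted p = 0.693). Disease stage was not tested apart from these.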

How the results depend on the processing

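The pseudocounts, the hybridisation, ACTB and plasma cell covariates, the run without the 4 bright arrays and the exact test of list levels were chosen after the data were seen. The named called genes held their direction in all 780 values under the alternatives run, and 340 of these passed. TOX2 passed in 29 and CHST2 in 28 of 33 alternatives (adjusted p up to 0.16 in both). Of 4110 values of named genes that were not called, 57 had the other sign and 19 passed.

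The number of genes, 32 as reported, was 6 with the mean of a gene's probe sets, 10 with every probe set on its own, 2 with no filter, 137 with the filter at the 60th percentile, 237 with trend and robust, 168 with array weights, 180 with the residual component, 221 at an adjusted p under 0.10 and 16 without X-linked genes. It was 8, 5 and 5 with the monocyte, platelet and erythroid covariates, 13 and 124 with pseudocounts of 1 and 64, and 0 by limma with the plasma cell covariate, with the hybridisation covariate and without the bright arrays (1354, 1151 and 1436 at an unadjusted p under 0.05). In these 3 runs with 0 genes the differences kept a median share of 0.898, 0.946 and 0.921 of their size while their SE grew 1.17, 1.30 and 1.21-fold. In the run without X-linked genes the sizes of the rest are fixed and 16 of the 30 genes still tested passed; the others crossed the threshold as the adjustment moved. For the other counts the cause was not tested. Leaving out 1 sample gave from 2 genes (without chronic sample 6) to 116 (without newly diagnosed sample 5), and every such count was more than 1.5 times away from 32.

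The number of lists, 5 as reported, was 3 with the filter at the 60th percentile and with quantile normalization. The exact test of list levels also gave 3: oxidative phosphorylation, apoptosis and heat shock and unfolded protein. Of these only oxidative phosphorylation is among the 5 reported. With camera's estimated correlation 0 passed, and 1 list, T helper 17, had an unadjusted p under 0.05. The 4 lists given by fry were oxidative phosphorylation, T helper 17, heat shock and unfolded protein and oxidative stress. With 1 sample left out the number of lists ran from 3 (without newly diagnosed sample 3, chronic sample 1 or chronic sample 2) to 8 (without newly diagnosed sample 5). Oxidative phosphorylation passed in 30 of 31 alternatives, cell cycle in 28, ribosomal protein in 24, T helper 17 in 20 and T cell identity in 15. All of these but the estimated correlation, fry and the exact test used camera's preset correlation, so the passes are not independent. The cell cycle list failed in exactly those alternatives (adjusted p = 0.799, 0.20 and 0.232). The ribosomal protein median reversed to -0.0466 under quantile normalization. With the hybridisation covariate the cytotoxic effector list passed upward with a median of 0.874, and the monocyte and neutrophil lists passed downward with -0.943 and -0.770; without the bright arrays the cytotoxic effector list passed upward (0.445) and the monocyte list downward (-0.580). For these reversals the cause was not tested.

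A replicate block was run because both groups number their samples. After the group mean of each gene was subtracted, samples of equal number correlated by -0.168 to 0.0745. By the same measure 0 of 6 chronic samples correlated best with the newly diagnosed sample of the same number. This check gave no sign of pairing, so the numbers were read as marking different patients. The block gave 0 genes by limma (1858 at an unadjusted p under 0.05) and 6 lists; the 32 genes kept a median share of 0.982 of their size while their SE grew 1.09-fold, and the cytotoxic effector list passed upward with a median of 0.357. The block leaves out the newly diagnosed sample without a partner and spends degrees of freedom on a pairing of which the check gave no sign.

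Signals near the background limit what the arrays can show: 357 tested genes lay at or under it in both groups.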

Other observations

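The 12 gene families behind the values in this part were drawn up after the values were seen, and all tests on them are of that kind. The family of 28 histone genes, nearly all of the replication-dependent kind, had 25 positive differences with a median of 0.44, and H2AC6 and H2BC12 were its called members. By camera with its preset correlation the adjusted p over the 12 families was 1.6e-04, and with an estimated correlation it was 0.0601. The preset correlation passed every family but the chaperonins, so that call does not set the histone genes apart. The mean histone level was 8.17 ± 0.26 in newly diagnosed and 7.63 ± 0.24 in chronic samples (two-sided exact permutation p = 0.00233). Without the called members the median of the other 26 was 0.41 (exact permutation p = 0.00874). The median was 0.46 under quantile normalization and 0.56 without the 4 arrays with bright hybridisation controls.

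Of 13 circadian clock genes, 9 had negative differences, with a median of -0.27, and RORA and NR1D2 were the called members. The adjusted p by camera was 8.8e-04 and with an estimated correlation 0.0406. The mean level was 8.81 ± 0.20 and 9.25 ± 0.10, and all 7 newly diagnosed samples, 8.44 to 9.03, lay below the 6 chronic samples, 9.10 to 9.38 (exact permutation p = 0.00117). The differences of CLOCK (-1.23), PER3 (-1.15) and CRY2 (0.46) did not pass the adjusted p over all genes. Without RORA and NR1D2 the other 11 genes had a median of -0.13 (exact permutation p = 0.0344, camera with estimated correlation p = 0.0613). The family median was -0.22 under quantile normalization and -0.43 without the bright arrays. The hour at which blood was drawn is not among the sample labels used here.

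Among the other families, 281 of 435 ZNF zinc finger genes had negative differences, 1 of them called, with a median of -0.18 (adjusted p with an estimated correlation 0.0457), and 31 of 45 ZBTB and ZMYM genes had negative differences, 0 called (0.0514). All 11 tubulin genes measured had positive differences, 0 called, with a median of 0.52 (0.195), and 76 of 95 respiratory chain genes had positive differences, 0 called, with a median of 0.24 (0.274). With an estimated correlation the replication licensing, mitochondrial ribosome and proteasome families had adjusted p-values of 0.331, 0.316 and 0.403. Those of the splicing factor, long non-coding and chaperonin families were 0.316, 0.213 and 0.706. By camera with its preset correlation the adjusted p was 8.2e-06 for respiratory chain, 5.5e-05 for ZNF zinc finger and 4.8e-04 for both tubulin and mitochondrial ribosome genes. Every other family but the chaperonins (0.615) was also under 0.05 by that test. The ZNF zinc finger median was -0.129 under quantile normalization and -0.106 without the bright arrays.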
